A study of Drosophila melanogaster with 4 samples.

How the data were processed

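Heads of unmated male Oregon-R flies fed TEA or normal food were compared on 4 cDNA arrays of the D12Kv1 type. Each biological replicate had 1 array, with a TEA and a control pool in opposite dyes. Per the labels' design text, heads were collected from frozen flies, cDNA was made from 10 µg of total RNA, labelled RNA was hybridised at 37 °C for 16 hours, and slides were scanned with GenePix Pro 6.0. The authors normalised ratios with Acuity 4.0, ignoring spots with raw intensity under 100 and under 2 times the mean background, per the labels' design text. They then kept spots with under 3% saturated pixels, no bad flag, a pixel regression R2 of at least 0.6 and a signal-to-noise ratio of at least 3, and passed spots analysable in at least 3 replicates to SAM 3.0. The settings of that last step are not given in the sources used here. No scanner values were used here, so signal over background cannot be shown per spot.

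The deposited values are log2 ratios, 1 column per array, normalised and filtered by the authors; a filtered spot is empty. The scale follows from the ceiling: 8 values stood at exactly 16.61, the log2 of a ratio of 1e+05. Column medians as deposited were -0.09, -0.077, -0.248 and -0.0545 in replicates 1 to 4, and mean linear ratios were 1.07, 1.01, 1.04 and 1.08. The direction of the ratio is not stated. It was read as Cy5 over Cy3, channel 1 over channel 2, and replicates 3 and 4, where the control carried Cy5, were multiplied to give TEA over control. Across probes, which are not independent replicates, Spearman correlations of the columns as deposited were 0.457 between replicates 1 and 2 and 0.340 between 3 and 4. Between dye orientations they were 0.002 for 1 and 3, 0.171 for 1 and 4, -0.238 for 2 and 3 and 0.010 for 2 and 4, and change sign once the swapped arrays are turned. By this measure arrays of 1 dye orientation resembled each other more than arrays of different orientation did. Pearson correlations after turning differed: 0.345 for replicates 2 and 3, against 0.335 for 1 and 2 and 0.171 for 3 and 4. The other pairs of opposite orientation lay between -0.023 and 0.033.

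The table holds each probe as 2 neighbouring spots. All 7609 pairs named on both spots shared a gene. A probe's value was the mean of its spots, and ceiling values were set to missing; both choices were made after the table was seen and before any fit. Duplicate spots had Spearman correlations of 0.724, 0.735, 0.733 and 0.622 in replicates 1 to 4, and differed by over 1 on the log2 scale in 3.74%, 3.47%, 5.15% and 6.72% of pairs. Gene symbols came from the platform annotation and were updated through gene identifiers to the RefSeq table of the Release 6 assembly, used for names and, in the test of neighbouring positions, for distances between genes. Of 7558 probes with 1 symbol, 7447 had an identifier in that table and took its symbol, changed or not. CG18217 had no match there and kept its symbol from the platform annotation. Of the 3150 tested probes, 1443 had 1 symbol, 14 had several and 1693 had none; a probe without a symbol is unnamed here, and no name was taken from a probe with several. No genome build is given in the sources used here, so no coordinates are printed.

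Probes with a value on at least 3 of 4 arrays were tested against 0 with limma 3.58.1 (lmFit and eBayes, intercept only, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The dye orientation is balanced, so a dye effect cancels in the mean of 4 arrays, but not for probes measured on 3. Replicates are pools of heads from separate sets of vials. Genes were the mean of a gene's probes per array, over 1379 genes. Of 20 gene lists and 10 marker lists, 15 had at least 5 measured genes and were tested with cameraPR (preset correlation 0.01, Benjamini-Hochberg over the 15), and also with camera at an estimated correlation and with fry on genes with 4 values. Errors are standard errors from the moderated fit unless SD is stated. Tests, lists and the rule for naming genes were fixed before the data were examined. The rule named up to 12 higher and 12 lower genes with the smallest p past the threshold and 1 sign on every array. It filled each direction to 12 with probes of 1 sign on all 4 arrays, and added the 4 members with the smallest p in each list of at least 5 measured genes, and all potassium channel members with Orct, Orct2 and CarT. Genes named outside it were chosen after their values were seen.

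Simulated data held 200 changed probes among 3150, at the moderated spread of the fit. The probe test recovered 10% of changes of 0.5, 80% of 1, 96% of 1.5 and 100% of 2 on the log2 scale. It made 10 false calls over all sizes. The gene test, on 1379 genes, recovered 58% of changes of 0.5 and 100% of 1, with 7 false calls. The adjustment is stricter where fewer features pass, and in the real data 20 probes and 12 genes passed. The recovery rates may therefore be too high for the real data. The list test called 100% of lists of 9 genes shifted by 0.4 and 3% of unshifted lists. All simulated values were drawn independently, without correlation between genes or a dye effect. These rates therefore do not bear on lists whose genes are correlated. Estimated correlations were 0.21 for the detoxification list and -0.06 for the feeding and starvation list. The alternatives covered the direction of the swapped arrays, a dye term, the filter on missing values, centring, scaling, array weights (statmod 1.5.0), robust moderation, genes in place of probes, a one-class SAM statistic at a false discovery rate of 5%, each replicate left out, and each dye orientation alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.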

Results

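Gene expression was measured in heads of unmated Drosophila melanogaster Oregon-R males, a wild-type laboratory strain, after feeding with tetraethylammonium chloride (TEA). TEA is an organic cation that blocks potassium channels and raises neuronal excitability. Flies received 16 mg/ml TEA in the food for 7 days, and control flies received normal food, at 30 flies per vial. Each of 4 biological replicates compared 1 pool of TEA heads with 1 pool of control heads on a 2-colour cDNA array. TEA was labelled with Cy5 in replicates 1 and 2 and with Cy3 in replicates 3 and 4. The arrays held log2 ratios for 6252, 6212, 5913 and 5445 of 27648 spots in replicates 1 to 4. Duplicate neighbouring spots were averaged to a probe, and 3150 probes with a value on at least 3 arrays were tested, of which 1443 named exactly 1 gene. The number of arrays limits the precision. The design also mentions a drug-withdrawal period, which was not analysed here.

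The first comparison asked which transcripts differed between heads of TEA-fed and control flies. No label states the direction of the deposited ratio; every array was read as Cy5 over Cy3, the order of the channels, so that replicates 3 and 4 change sign. In this reading CG9689 rose and CG3777 and Not11 fell with TEA. CG9689 stood at a log2 ratio of 1.43 ± 0.17 (SE, n = 4; limma adjusted p = 0.038), a 2.69-fold higher level with TEA. CG3777 stood at -1.43 ± 0.14 (SE, n = 4; limma adjusted p = 0.035), and Not11, a subunit of the CCR4-NOT complex that shortens mRNA tails, at -1.11 ± 0.12 (SE, n = 4; limma adjusted p = 0.038). Each of these 3 genes had 1 sign on all 4 arrays. In all, 20 probes passed the threshold, 3 higher and 17 lower with TEA, with sizes from 0.96 to 3.21 on the log2 scale, and 17 of the 20 are unnamed here. The unnamed probe with the largest size, at spots 3141 and 3142, stood at -3.21 ± 0.22 (SE, n = 4), and the next by p, at spots 7419 and 7420, at -1.73 ± 0.14 (SE, n = 4). The direction stays open: ratios at the software ceiling were positive in every column that held any, and all 4 column medians lay below 0, which argues only against columns turned after normalization. If the ratio ran Cy3 over Cy5 on every array, all signs would turn. If the swapped arrays had been quantified the opposite way before normalization, limma called 0 probes, with 353 at an unadjusted p under 0.05 against 283 in the reading used, and the log2 ratio became 0.07 ± 0.63 (SE) for CG9689, -0.03 ± 0.63 for CG3777 and 0.05 ± 0.49 for Not11.

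The other named probes had 1 sign on all 4 arrays, and none of them passed the threshold at the probe level. Desat1, a fatty acid desaturase, had a log2 ratio of 1.08 ± 0.24 (SE, n = 4). A probe for apolpp, the precursor of the haemolymph lipid carrier lipophorin, had 1.05 ± 0.20 (SE, n = 4), and a second apolpp probe had 0.52 ± 0.13. CG9663 had 0.95 ± 0.21 and trbd, a deubiquitinating enzyme, 0.86 ± 0.15. A second trbd probe stood at -0.03 ± 0.12, so the probes for trbd disagreed. The remaining 7 positive probes lay between 0.41 for wat, a fatty acyl reductase, and 0.66 for Gbs-70E, a glycogen-targeting subunit of protein phosphatase, with Idgf6, a chitinase-like secreted protein, at 0.54. On the lower side, CG18217 had a log2 ratio of -0.83 ± 0.12 (SE, n = 4), CG31793 -0.80 ± 0.19, Rlb1 -0.67 ± 0.13 and COX6AL, a cytochrome c oxidase subunit, -0.58 ± 0.12. The remaining 6 negative probes lay between -0.64 for CG9471 and -0.35 for Gdh, glutamate dehydrogenase, with the kinase Nuak at -0.37. These probes, filled in by rank to 12 per direction, are described and not called. With the swapped arrays not turned, 9 of the 24 named probes took the other sign, 6 of the higher and 3 of the lower; the log2 ratio was then 0.50 ± 0.48 (SE) for Desat1, -0.28 ± 0.47 for apolpp, 0.43 ± 0.42 for CG9663, -0.22 ± 0.38 for trbd, 0.05 ± 0.37 for CG18217, -0.09 ± 0.39 for CG31793, -0.09 ± 0.31 for Rlb1 and -0.09 ± 0.27 for COX6AL.

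**Figure D1:**
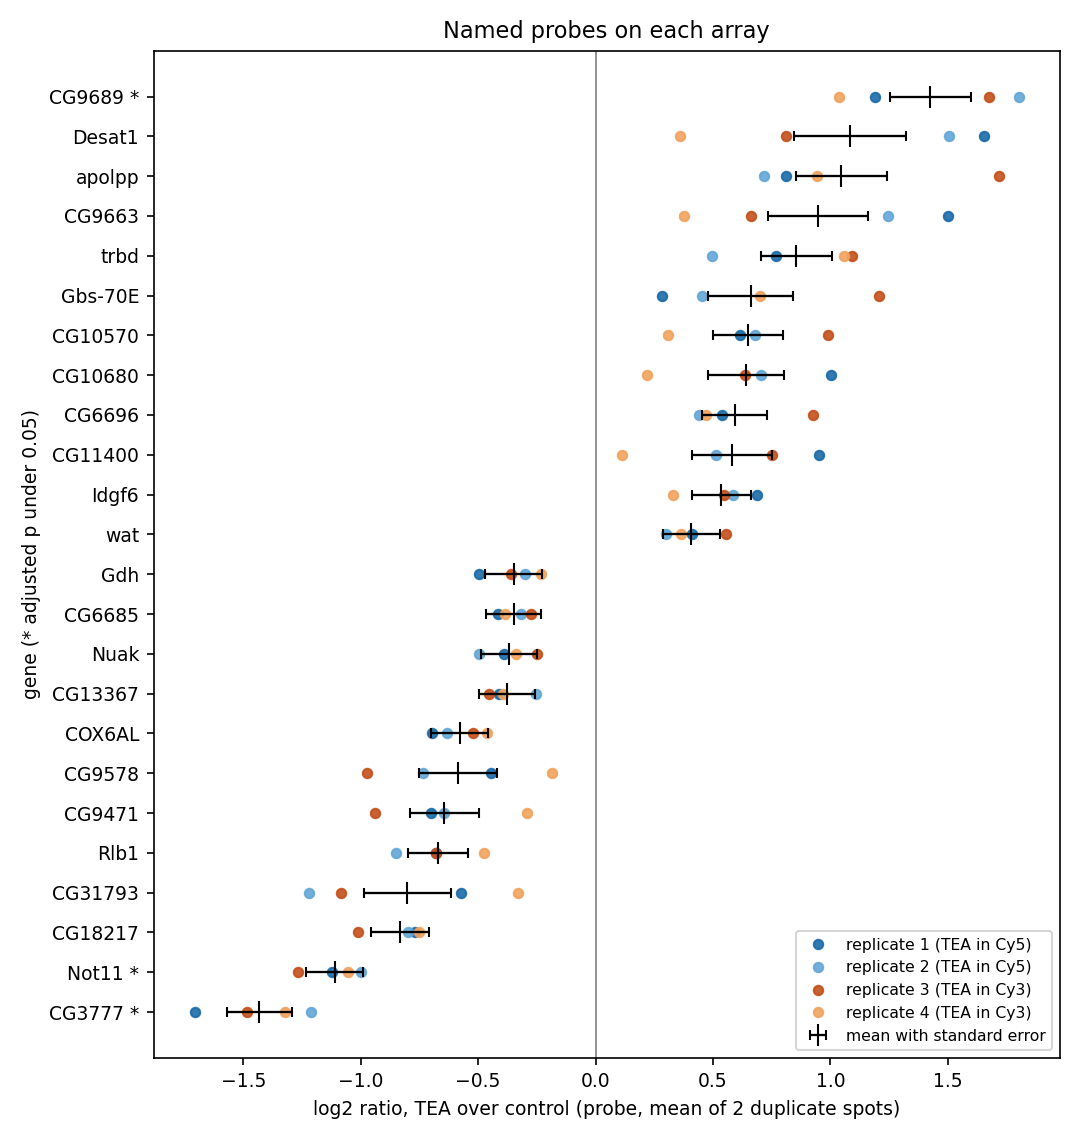
Log2 ratio of TEA over control (x axis) for the 24 named probes (y axis), with 1 point per array and the mean with its standard error in black; asterisks mark the 3 probes at an adjusted p under 0.05. All 4 points of each gene lie on 1 side of 0, as the selection required, with CG9689 highest at a mean of 1.43 and CG3777 lowest at -1.43.

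When the probes of a gene were averaged and 1379 genes tested, 12 genes passed, 6 higher and 6 lower with TEA. The higher genes were CG9689, Desat1, apolpp, CG9663, dpr16, a cell-surface protein of the immunoglobulin family (1.09 ± 0.20, SE, n = 3; limma adjusted p = 0.022), and Prps, a phosphoribosyl pyrophosphate synthetase (0.85 ± 0.16, SE, n = 3; limma adjusted p = 0.028). The lower genes were CG3777, Not11, CG18217, Rlb1, CG31793 and Sec20, a membrane fusion protein of the SNARE type (-1.07 ± 0.16, SE, n = 3; limma adjusted p = 0.0088). At the gene level apolpp stood at 0.78 ± 0.15 (limma adjusted p = 0.022) and Desat1 had an adjusted p of 0.021. Named genes without 4 values were outside the rule for naming and are given because the count is small. The fit over genes moderated the spread with 10.3 prior degrees of freedom against 3.29 over probes, which lowers p for the same values. Without replicate 4 only CG3777 and CG9689 passed (limma adjusted p = 0.037 each), although none of the 12 means moved towards 0. Not11 then had a limma adjusted p of 0.058, Desat1 0.098 and apolpp 0.133. Rlb1 (0.210) and CG31793 (0.147) lost the call without replicate 2 and Prps (0.056) without replicate 1. All 12 passed without replicate 3. With the swapped arrays not turned, 0 genes passed, and the gene means were 0.69 ± 0.37 (SE) for dpr16, 0.24 ± 0.33 for Prps, -0.36 ± 0.39 for Sec20 and -0.11 ± 0.29 for apolpp.

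Several of these genes sat beside positions that moved the same way. Positions here are the order of probes in the table. The print layout was not in the data used here, so whether such positions adjoin on the slide is not known. CG3777, Not11 and COX6AL occupied consecutive positions, after an unnamed position at -1.73, and were followed by positions at -0.30 and -0.22, while the named position before the series, Trm7-34, stood at 0.22. CG9663 followed Desat1 directly and trbd followed the higher apolpp probe. CG18217, Rlb1 and CG9471 followed unnamed positions at -0.88, -0.81 and -1.33. Of the 12 lower named probes, 8 had a tested preceding position, and in 6 of these it lay further from 0 in the same direction; among the 12 higher probes it was 2 of 2. CG9689 was followed by GXIVsPLA2 at 0.46, and its preceding position was not tested. Of the 20 called probes, 9 stood next to another called probe, against at most 6 in 10000 random sets of tested probes.

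**Figure D2:**
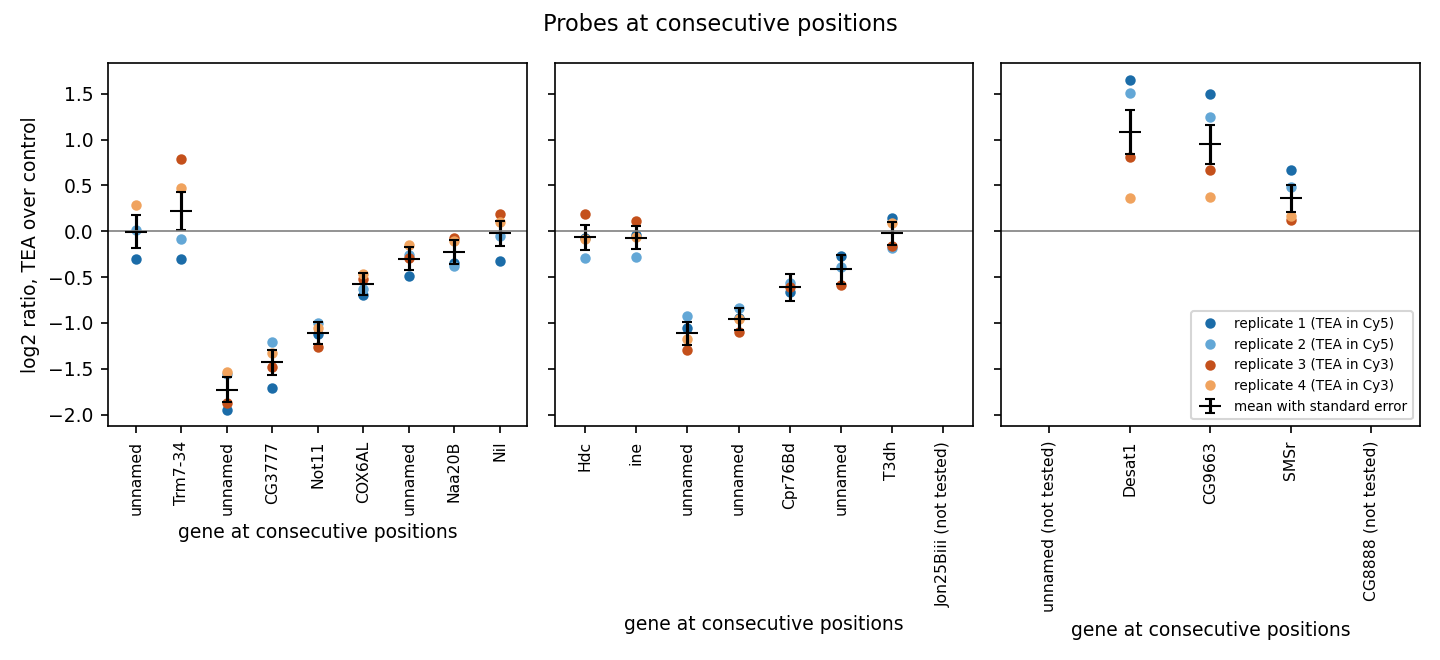
Log2 ratio of TEA over control (y axis) of probes at consecutive positions (x axis, in table order), with 1 point per array and the mean with its standard error in black, in 3 stretches. Values run from -1.73 through CG3777, Not11 and COX6AL to -0.22 in the left panel, from -1.11 to -0.42 in the middle panel and from 1.08 at Desat1 to 0.36 at SMSr in the right panel.

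The count of 20 probes rested on all 4 arrays: limma called 4 probes without replicate 1, 0 without replicate 2 (178 at an unadjusted p under 0.05), 1 without replicate 3 and 0 without replicate 4 (331), and the 2 arrays with TEA in Cy5 alone gave 3 and those with TEA in Cy3 alone 0 (300). It was 0 with arrays centred on their medians (310), with a dye term (427) or with each spot tested on its own (497). At an adjusted p under 0.10 there were 16 probes with centred arrays (smallest 0.072), 40 with a dye term (smallest 0.065) and 42 single spots (smallest 0.069), against 33 probes in the fit without these changes. The one-class SAM statistic called 30 probes, 4 higher and 26 lower. Its false discovery rate was estimated from only 8 sign patterns of the arrays, 1 of them the real one.

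Gene groups fixed in advance were compared next, on gene means, to ask which functions moved as a whole. Genes of xenobiotic detoxification were shifted upwards with TEA: their median log2 ratio was 0.21 over 18 measured genes, 14 of them above 0 (cameraPR adjusted p = 0.026). The call was lost with an estimated correlation (adjusted p = 0.893) and by fry (adjusted p = 0.607), both over the 14 genes with 4 values. Of the 18, 10 were cytochrome P450 genes, all above 0, so every member not above 0 was of another kind. None of the 18 rose or fell individually, and none passed when adjusted over the list alone. The smallest p belonged to the cytochromes P450 Cyp313a1 (0.40 ± 0.14, SE, n = 4), Cyp28d1 (0.36 ± 0.15, SE, n = 4) and Cyp4ac1 (0.36 ± 0.16, SE, n = 3) and to the glutathione transferase GstE12 (0.35 ± 0.14, SE, n = 4). By array the list's medians were 0.29, 0.20, 0.32 and -0.05 in replicates 1 to 4. On the arrays with TEA in Cy5 alone the list passed (adjusted p = 0.00017), and on those with TEA in Cy3 alone it did not (adjusted p = 0.799), where its median of 0.19 lay close to the 0.17 of all genes and the test pointed downwards. The call also ended with a dye term (median 0.21, adjusted p = 0.170), with median-centred arrays (0.18, adjusted p = 0.055), without replicate 1 (0.18, adjusted p = 0.653) and without replicate 2 (0.21, adjusted p = 0.629), so the median kept its sign where the call ended. With the swapped arrays not turned the median was 0.08 (cameraPR adjusted p = 0.0029).

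Genes of feeding and starvation response were also shifted upwards, with a median log2 ratio of 0.19 over 9 measured genes, 6 of them above 0 (cameraPR adjusted p = 0.026). The call was lost with an estimated correlation (adjusted p = 0.318) and by fry (adjusted p = 0.151), both over only the 5 of these genes with 4 values. Of the 9, 1 rose, Desat1, over all genes tested, and 4 passed when adjusted over the list alone. The 4 were Desat1 (1.08 ± 0.20 at the gene level, SE, n = 4), the lipid droplet protein Lsd-2 (0.58 ± 0.16, SE, n = 4), the fatty acid synthase FASN1 (0.45 ± 0.14, SE, n = 4) and the lipase bmm (0.45 ± 0.16, SE, n = 4). Below 0 were the sugar-responsive transcription factor sug (-0.26 ± 0.16, SE, n = 3), the maltase Mal-A2 (-0.19 ± 0.17, SE, n = 3) and mdy, an enzyme of triglyceride synthesis (-0.07 ± 0.17, SE, n = 3). The list joins genes of fat synthesis and of fat breakdown, so its shift does not tell feeding from starvation. By array its medians were -0.08, 0.09, 0.81 and 0.36 in replicates 1 to 4, against -0.10, -0.09, 0.26 and 0.06 for all genes. Without Desat1, whose position neighbours CG9663, the unadjusted p was 0.080. Beside this group, the measured head fat body markers stood at 0.78 for apolpp, 0.45 for FASN1, 0.33 ± 0.20 (SE, n = 3) for bgm and -0.00 ± 0.14 for Lsp2. The list passed with TEA in Cy5 alone (median 0.07, adjusted p = 0.0035) and with TEA in Cy3 alone (0.58 over 5 genes, adjusted p = 0.049). It did not pass with median-centred arrays (median 0.20, adjusted p = 0.055), with centred and scaled arrays (0.19, adjusted p = 0.055), or without replicate 1 (0.31, adjusted p = 0.115), replicate 2 (0.27, adjusted p = 0.146) or replicate 4 (0.23, adjusted p = 0.052), each with a median close to or above that of all arrays. With the swapped arrays not turned the median was -0.20 (adjusted p = 0.423).

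**Figure D3:**
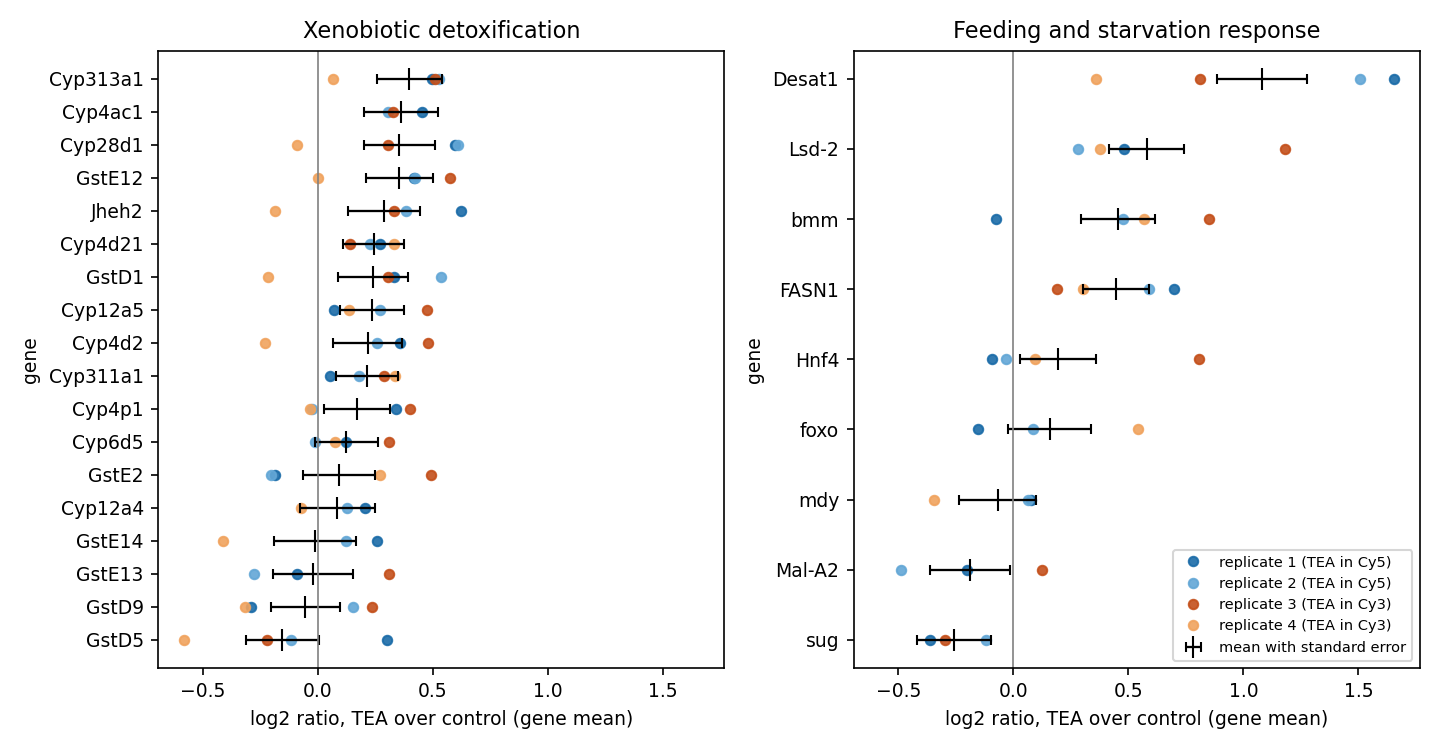
Log2 ratio of TEA over control (x axis) of the measured genes of the detoxification list (left, 18 genes) and the feeding and starvation list (right, 9 genes), with 1 point per array and the mean with its standard error in black. In the left panel 14 means lie above 0, the highest being Cyp313a1 at 0.40; in the right panel Desat1 lies highest at 1.08 and sug lowest at -0.26.

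Potassium channels, their subunits and partners were represented by 4 measured genes of 25, and none passed over all arrays. Shab stood at -0.33 ± 0.21 (SE, n = 3), the slowpoke-binding protein Slob at 0.19 ± 0.19 (SE, n = 4), Sh at 0.08 ± 0.16 (SE, n = 4) and Dyb at -0.04 ± 0.18 (SE, n = 4). Shab had -0.74 and -0.57 in replicates 1 and 2, with TEA in Cy5, and 0.31 in replicate 3, with TEA in Cy3. It had no value in replicate 4, so its sign split by dye orientation. Without replicate 3 the mean of the other 2 was -0.66 (limma adjusted p = 0.042). The same 2 values in the fit to TEA in Cy5 alone gave a limma adjusted p of 0.00041. The p therefore depends on the fit and not on the spread of Shab. Dyb split by dye as well, at -0.44 with TEA in Cy5 alone (limma adjusted p = 0.036) and 0.35 with TEA in Cy3 alone (limma adjusted p = 0.377). Sh also did, at -0.23 with TEA in Cy5 alone and 0.39 with TEA in Cy3 alone, and passed in neither. On arrays of 1 dye orientation a dye effect cannot be told apart from an effect of TEA. The organic cation transporters Orct, Orct2 and CarT had no tested probe. Among other channels and pumps, none of 3 sodium, calcium and chloride channel genes passed (median -0.03), nor any of 3 ion pump genes, whose highest value was 0.35 ± 0.18 for nrv3, a subunit of the sodium pump.

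Neuronal groups did not pass as a whole. Synaptic vesicle genes had a median of 0.14 over 8 measured genes (cameraPR adjusted p = 0.829), with Sap47 at 0.33 ± 0.20 and alphaSnap at 0.27 ± 0.16. Its array medians split by dye, -0.33 and -0.09 with TEA in Cy5 and 0.65 and 0.27 with TEA in Cy3. It passed upwards with TEA in Cy3 alone (median 0.60 over 6 genes, adjusted p = 0.049), not with TEA in Cy5 alone (-0.24, adjusted p = 0.675), and passed downwards with the swapped arrays not turned (-0.36, adjusted p = 0.018). The median of the 14 measured neurotransmitter genes was -0.00 (cameraPR adjusted p = 0.931). Its members with the smallest p were glutamine synthetase Gs2 (0.46 ± 0.14, SE, n = 4; limma adjusted p = 0.245) and the glutamate-gated chloride channel GluClalpha (0.44 ± 0.15, SE, n = 4; limma adjusted p = 0.363), neither past the threshold. Neuropeptide genes had a median of 0.00 over 8 genes (cameraPR adjusted p = 0.931), with Pal2 at 0.27 ± 0.17 and Mip at -0.12 ± 0.15. Phototransduction and eye genes had a median of 0.06 over 10 genes (cameraPR adjusted p = 0.931), within which santa-maria stood at -0.45 ± 0.16 (SE, n = 3) and arrestin Arr1 at 0.40 ± 0.15 (SE, n = 4). Of the 5 measured clock genes, Pdp1 stood at 0.46 ± 0.26 (SE, n = 3) and per at 0.03 ± 0.15 (cameraPR adjusted p = 0.931 for the group).

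Stress, energy and protein synthesis groups did not pass either. The 6 immune genes had a median of 0.11 (cameraPR adjusted p = 0.931), with the antimicrobial peptide Drs at 0.20 ± 0.14. The 5 chaperone genes had a median of 0.11 (cameraPR adjusted p = 0.931), with l(2)efl at 0.15 ± 0.15 and DnaJ-1 at 0.18 ± 0.17, the mean of 3 probes at 0.36, -0.29 and 0.47 that disagreed. Oxidative phosphorylation had a median of 0.02 over 25 genes (cameraPR adjusted p = 0.931). Of these, 1 passed when adjusted over the list alone, COX6AL, which sits directly after Not11, and ATPsynC stood at 0.36 ± 0.14. Cytosolic ribosomal proteins (17 genes, median 0.02), mitochondrial ribosomal proteins (10 genes, 0.02) and proteasome subunits (7 genes, -0.02) had cameraPR adjusted p of 0.931 each, with RpL39 at 0.42 ± 0.16, mRpS9 at -0.19 ± 0.13 and Rpt3 at 0.21 ± 0.17. The cytosolic ribosomal list passed downwards with TEA in Cy3 alone (median 0.027, adjusted p = 0.049) and upwards with the swapped arrays not turned (0.02, adjusted p = 0.0097). Glycolysis and trehalose genes had a median of 0.09, 10 of 12 above 0 (cameraPR adjusted p = 0.638), with the aldolase Ald1 at 0.61 ± 0.21. Lists with fewer than 5 measured genes were not tested: the medians were 0.18 for 3 antioxidant genes, 0.03 for 3 vacuolar ATPase genes and 0.13 for 4 cytoskeletal genes, with Tctp at 0.44 ± 0.16.

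Values of group members that did not pass often depended on 1 array or on the reading of the ratio. Of 92 such gene means, 41 shrank by over 1.5 times or changed sign without replicate 3, against 20, 14 and 21 without replicates 1, 2 and 4. After turning, the median of all tested probes was 0.24 in replicate 3, against -0.09, -0.08 and 0.055 in replicates 1, 2 and 4. The fit did not centre the arrays, so this offset of replicate 3 enters the gene means. Without replicate 3 the log2 ratio was 0.03 for Sap47, 0.14 for alphaSnap, 0.09 for Pal2, 0.02 for Pdp1, 0.30 for Ald1, 0.13 for nrv3, 0.28 for Tctp and -0.01 for Rpt3. Pdp1 passed without replicate 1 (0.91, limma adjusted p = 0.016), Ald1 without replicate 1 (0.75, limma adjusted p = 0.016) or replicate 2 (0.78, limma adjusted p = 0.040), and COX6AL (-0.60, limma adjusted p = 0.016) and FASN1 (0.53, limma adjusted p = 0.042) without replicate 3. Some members passed in 1 dye orientation only. With TEA in Cy3 alone Ald1 stood at 1.07, Sap47 at 0.74 and bmm at 0.71, against 0.14, -0.08 and 0.20 with TEA in Cy5 alone. With TEA in Cy5 alone Picot stood at -0.64 and Cyp28d1 at 0.60, against 0.13 and 0.11 with TEA in Cy3 alone. With a dye term, Ald1, Lsd-2, COX6AL, Pdp1, Gs2, bmm, FASN1, Tctp, GluClalpha, Arr1 and Cyp313a1 passed. That fit gave genes measured on all 4 arrays equal p for equal log2 ratios, whatever their spread between arrays. Arr1 and Cyp313a1, both at 0.40, had a limma adjusted p of 0.034 each. These calls therefore ignore each gene's own spread, and the same model called 0 probes. The fits without replicate 1, without replicate 2 and on each dye orientation alone likewise ordered p by size for genes with no missing value. Without replicate 1, nrv3 and Tctp, both at 0.50, had a limma adjusted p of 0.205 each. Calls from those fits, such as those of Pdp1 and Ald1, do not weigh spread either, and Pdp1 had no value in replicate 4. With the swapped arrays not turned, 53 of the 92 took the other sign, with Ald1 at -0.46, Pdp1 at -0.43, Sap47 at -0.41 and alphaSnap at -0.31. The list medians were then -0.16 for neurotransmitter, -0.22 for neuropeptide, -0.16 for phototransduction, -0.24 for clock, 0.03 for immune, -0.13 for chaperone, -0.07 for oxidative phosphorylation, -0.15 for mitochondrial ribosomal, -0.13 for proteasome, -0.05 for glycolysis and trehalose (4 of 12 above 0) and -0.07 for muscle genes, against -0.13 for all genes.

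Markers of cell types in or near the head showed no gene past the threshold apart from apolpp, at the gene level. The 5 muscle markers had a median of -0.08 (cameraPR adjusted p = 0.931), with Act88F at 0.23 ± 0.16 and Mlc2 at -0.08 ± 0.14. Medians over fewer markers were 0.08 for 3 glial genes, 0.09 for 4 photoreceptor genes, 0.39 for 4 head fat body genes, -0.15 for 3 midgut genes and -0.11 for 2 Malpighian tubule genes. Single genes stood for haemocytes (Col4a1, 0.03), testis (ocn, -0.18) and female-enriched transcripts (Yp2, 0.05). No neuron marker had a tested probe. When adjusted over the list alone, 1 glial marker (Gs2) and 2 head fat body markers (apolpp and FASN1) passed; apart from the feeding and oxidative phosphorylation lists, no other gene or marker list had such a member.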

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

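The tests in this part were set in advance: in 117 sets of 4 array values, the gap between the most distant array and its nearest neighbour was divided by the range and set against Dixon's 95% critical value for 4 samples. The rule picks out about 1 set in 20 by chance, or 5.85 of 117, and it picked 6. No explanation was tested for these values. The arrays were not centred, and replicate 3 had the highest median of all tested probes after turning, 0.24. For apolpp, replicate 3 stood at a log2 ratio of 1.18 and the other arrays between 0.61 and 0.68. For ATPsynC, a subunit of the ATP synthase, replicate 3 stood at 0.71 and the others between 0.22 and 0.26. The median of the neurotransmitter list was 0.67 in replicate 3 and between -0.12 and -0.04 in the others. For Cyp313a1, replicate 4 stood at 0.064 and the others between 0.49 and 0.53, so the value of this P450 rests on the other arrays. For the chaperone Droj2, replicate 1 stood at -0.27 and the others between 0.21 and 0.27. The Spearman correlation between duplicate spots was 0.622 in replicate 4 and between 0.724 and 0.735 in the others.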

How the results depend on the processing

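Alternatives with ceiling values kept, spots more than 1 apart left out, spots tested singly, a threshold of 0.10 and the feeding list without Desat1 were chosen after seeing the data. The count of 20 probes became 0 with the swapped arrays not turned, with a dye term, with arrays centred on their medians, on the arrays with TEA in Cy3 alone and with each spot on its own. It became 3 with TEA in Cy5 alone, 12 for genes in place of probes, 31 with duplicate spots over 1 apart left out (18 of the 20 shared) and 33 at an adjusted p under 0.10. Leaving out each replicate gave 0 to 4 probes, 0 of them without replicate 2 or 4; with 3 arrays the dyes are unbalanced and fewer values enter, and the cause was not tested further. It was 30 by SAM (20 shared) and stayed between 16 and 27 for the stricter and looser filters on missing values, centring with scaling (16, of which 12 were shared and 2 higher), array weights, robust moderation and ceiling values kept. The share of higher calls, 15%, was 0% where calls were made without replicate 1 or 3 (0 in each) and with TEA in Cy5 alone, and 50% for genes. The count of 2 gene lists became 1 with a dye term and with centred and scaled arrays, and 0 with median-centred arrays, with an estimated correlation and by fry; leaving out each replicate gave 0 to 2, and it was 3 with TEA in Cy3 alone and with the swapped arrays not turned. Among results called in either fit, those that reversed were the synaptic vesicle list at -0.36, the feeding list at -0.20, Not11 at 0.050 and the gene means of apolpp at -0.11 and CG18217 at 0.049, all with the swapped arrays not turned, and, in the direction of the list test, detoxification at 0.19 and cytosolic ribosomal proteins at 0.027 with TEA in Cy3 alone. The cause of these changes was not tested beyond the direction of the ratio. The 12 called genes stayed past the threshold in 144 comparisons and lost the call in 39, and the 3 called named probes in 20 and 27, beside 3 and 1 that reversed. Without replicate 4 all gene calls but those of CG3777 and CG9689 ended. With TEA in Cy3 alone those of Desat1 (limma adjusted p = 0.071), CG9663 (0.127) and Rlb1 (0.075) ended. The dye-term fit, counted here, gave genes of equal log2 ratio on 4 arrays equal p whatever their spread. The gene fits without replicate 1, without replicate 2 and on each dye orientation alone, also counted, ordered p by size for genes with no missing value. A gene call kept in these fits therefore reflects the size of the ratio and not its spread between arrays. Values of genes that had not passed were compared with 1 SD between arrays: 1343 comparisons of gene means and 313 of named probes stayed the same, 47 and 3 became past the threshold in the same direction, and 48 and 20 moved, among them the probes of apolpp to -0.28 and trbd to -0.22 with the swapped arrays not turned. The median of all tested probes was 0.03, and 0.00 after centring.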

Other observations

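The tests of carry-over between positions, of the named neighbouring pairs, of the ratio's direction, of other sign patterns, of fat body tissue and of gene families were chosen after the results they bear on were seen. Grouping measured genes by the letters their symbols share gave 9 families of at least 5 genes. Cytochrome P450 genes (Cyp) stood apart: all 12 measured had a mean log2 ratio above 0, from 0.08 to 0.40, with a median of 0.23 (limma's cameraPR, adjusted p = 0.0083 over the families). None of the 12 passed individually, 10 of them are in the detoxification list, so this is not independent of it, and with an estimated correlation the p was 0.119. The median stayed at 0.19 with centred arrays and 0.20 with centred and scaled arrays, all 12 above 0 in each, and was -0.00 with 6 of 12 above 0 when the swapped arrays were not turned, where the median of all genes was -0.13. In that reading the family still lay above other genes, with a p of 0.045, and with TEA in Cy5 alone the p was 0.00069 and with TEA in Cy3 alone 0.361. Among the other families, the 5 Rab genes, small GTPases of membrane traffic, had a median of 0.15, all above 0 (cameraPR adjusted p = 0.680), the 9 odorant-binding proteins (Obp) a median of 0.16 (cameraPR adjusted p = 0.760), and the 12 eIF translation factors a median of 0.12 (cameraPR adjusted p = 0.760).

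Called probes lay together at neighbouring positions in table order, which need not be neighbours on the slide. Values fell off towards later positions from CG3777 through Not11 to COX6AL, but not everywhere. A value of -0.74 came before the -1.33 that precedes CG9471, and called unnamed probes at -1.52 and -1.54 stood before and after the one at -3.21. Noise of single arrays is argued against as the whole cause, because the median Spearman correlation between a probe on 1 array and the next position on another was 0.117, above the highest of 100 shuffles, 0.034, although within an array it was 0.459, so part of the likeness is not shared between arrays. Genes lying together in the genome are argued against for the named positions: 0.463% of 4535 neighbouring named pairs lay within 100 kb, above the highest of 100 shuffles (0.349%) but rare, and 0 of the 10 pairs of 1 sign that hold a gene of the naming rule did. For sharing with positions on either side, uncalled neighbours had a median of 0.069 signed by the called probe. It lay within the central 95% of draws, -0.140 to 0.142, which the bound set in advance counts against sharing. That bound left out the called neighbours and joined 7 following values with a median of 0.56 to 6 preceding ones with -0.02. A condition on each side, not in the bound set in advance, was therefore added. The following median lay above the draws' range, so sharing is left open. Signal carried only to the following position stays open for the called probes, as at 228 uncalled local peaks the difference between sides was 0.026 (highest of the draws that swapped sides 0.029) and at the 28 peaks over 0.5 it was 0.110 (highest 0.169), so neither passed its draws, and it may be that CG3777, Not11, COX6AL, CG9663 and trbd carry part of a neighbour's ratio, with a real change of each gene equally untested.

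For the direction of the ratio, a turn of the swapped columns after normalization is argued against, as 0 of their 4 ceiling values stood at the negative ceiling. A swapped ratio set before normalization cannot be told apart from the reading used, since ceiling and median would keep their sign; under it 0 probes passed. The real sign pattern of the arrays called 20 probes and the highest of the other patterns 0, but only 8 patterns exist, of which 1 gave as many as the real one, the real one itself, so no share under 0.05 can be reached.

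Desat1, Lsd-2, FASN1 and bmm had a median log2 ratio of 0.52, and a hypothesis is that TEA heads held more fat body tissue. The other fat body markers, apolpp, bgm and Lsp2, had a median of 0.33, with a standard error of up to 0.20, and the bound set for this test was 0.26, so more tissue cannot be told apart from a change within fat body cells. That median is the value of bgm, which had no value in replicate 3 and so was not balanced for dye. With TEA in Cy5 alone bgm stood at 0.63 and without replicate 1 at 0.18, so the test rests on 1 gene that varied between arrays. Lsp2 at -0.00 and apolpp at 0.78 lay apart, which goes against an equal rise of all markers. Neighbouring positions as a source were tested by leaving out Desat1, the 1 of 9 members with a neighbour that moved alike: the median of the rest was 0.18 with a standard error of 0.14, which does not separate the bounds set for this test. A change in feeding with TEA may also account for the shift and was not tested.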
